A study of Homo sapiens with 58 samples.

How the data were processed

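By the submitters' notes, reads were checked with FastQC 0.11.9, trimmed with Trim Galore 0.6.5, aligned to GRCh38 with STAR 2.7.3a and counted per gene with RSEM 1.3.3. The libraries were made with the MGIEasy RNA Directional kit from 1 µg of total RNA with an integrity number above 7, and read as 100 bp pairs on an MGIseq system. RSEM shares reads that fit several genes among them, so the counts of close paralogs, pseudogenes and readthrough genes depend on that allocation. Most such genes were left out of the text, but the metallothionein, AKR1C and GSTA genes were kept. Counts of metallothionein genes that fell are therefore not counts of fully separate measurements. The values as deposited were expected counts, which the authors estimated with RSEM from the aligned reads, and no scaling between libraries was found in them. Of their nonzero values 76.07% were whole numbers, and they were rounded before testing. Of the 60675 gene identifiers, 57055 received a symbol, 56558 from a current table and 497 from GENCODE release 29, and 26619 had no reads in any library. A symbol that several identifiers share was given to the one with the most reads, and the other 1167 identifiers stayed in the table without it. The table held 209 further columns that the sample labels did not map to these libraries, and they were not used here. The wortmannin control named in the series text was not analysed here. By that text, some samples had been left out by the submitters for low RNA concentration.

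Genes with at least 1 CPM in at least 3 libraries entered the test, which left 13945. Counts were scaled by TMM (factors from 0.878 to 1.035, the lowest in Coptidis Rhizoma) and fitted by edgeR quasi-likelihood with 1 mean for each of the 24 groups over all 58 libraries. The common dispersion was 0.00181, a coefficient of variation of 4.25% between replicates. No replicate was a copy of another of its group, since the lowest chi-square between replicates was 2.18 per gene. The p-values were two-sided and adjusted by Benjamini-Hochberg within each comparison at 0.05. Fold changes came from the edgeR fit, for which no prior count was set. Log2 CPM for the principal components, the correlations between libraries and the GC trends used a prior count of 2. A 2-fold count is of called genes with a fold of at least 2 either way. In groups of 1 library the spread was that of the other groups, so their counts rest on an assumption and no p across genes is given for their lists. The comparisons, the 31 gene lists, the rule for named genes and all alternatives except those named as added later were fixed before the data were examined.

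That rule took, at the high dose against the vehicle, the 10 called genes with the largest rise and the 10 with the largest fall among those with a symbol, a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups. It added up to 4 called members of each list, largest change first, and a panel that included CYP1A1, HMOX1, DDIT3, ASNS, HMGCS1, CYP3A4, CYP7A1, ALB, CDKN1A, MT1X, PCK1 and FGF21. In the other comparisons it took the 5 largest each way and the panel, and in groups of 1 library the 10 largest each way outside the range of the vehicle libraries, list members by size and the panel. CYP3A4, CYP7A1 and FGF21 had too few reads to enter the test. Some genes that the rule names are not reported here. List members named in comparisons where the rule gives none were chosen after their values were seen. CYP1A2, MT1M and HSPA6 had almost no reads in 1 of the groups compared, so no fold is given for them.

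The lists covered AhR targets, NRF2 targets, ATF4 and CHOP targets, endoplasmic reticulum chaperones, heat shock genes, metallothioneins (with the zinc exporter gene SLC30A1), cholesterol synthesis and uptake, fatty acid synthesis and LXR targets, PPARA and fatty acid oxidation, bile acid and FXR genes, PXR and CAR targets, secreted plasma proteins, gluconeogenesis and FOXO1 targets, hypoxia and glycolysis, p53 targets, mitosis, DNA replication, NF-kB and acute phase, interferon response, autophagy and lysosome, immediate early and SRF or YAP targets, circadian clock, respiratory chain genes of the nucleus and of the mitochondrial DNA, ribosomal proteins and replication-dependent histones. Some genes are on several lists, such as GDF15, SLC7A11 and FGB. Another 5 lists held markers of fibroblasts, leukocytes, endothelium, intestine and lung. Camera tested 26 lists in 31 comparisons with a preset correlation of 0.01, adjusted over the 806 tests, and was repeated with a correlation estimated for each list. Lists with fewer than 5 measured genes were not tested. For groups of 1 library the median of each list was compared with 10000 random lists.

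The method was tried on counts simulated from these libraries with 200 of 13945 genes changed. At folds of 1.2, 1.5 and 2, edgeR recovered 59.7, 88.1 and 100% of them with 3 libraries against 3, 40.3, 92.5 and 95.5% with 2 against 3, and 25.4, 83.6 and 95.5% with 1 against 3. There were 6 false calls among 171, 3 among 155 and 3 among 139. With nothing changed edgeR called 0 genes in each of 2 comparisons. A list of 22 genes lowered 1.2-fold was called by camera (adjusted p = 3.7e-103), and 0 of 492 other list tests were. The simulated genes varied independently of one another, so this cannot show how camera fares with correlated genes. Lone libraries were drawn with the spread of the others, so their recovery rests on that assumption too. Few genes were changed, as many raised as lowered. The trial therefore does not cover scaling where many genes move, as at Scutellariae Radix high, where 56.7% of the tested genes were called. A trend linear in GC content added to a library gave 6462 called genes, and 0 once that trend was taken out. The smooth correction can hold a linear trend, and no trend with length was simulated, so other trends were not tried. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.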

Results

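The series measured messenger RNA in HepG2, an established cell line from a human hepatocellular carcinoma, after 24 h of treatment with herbal extracts. The 8 extracts of 1 batch of the series were used here. Sayeok-tang and Bojungikgi-tang, which are multi-herb formulas, were hot water extracts. The others were 70% ethanol extracts of single herbs, Zingiberis Rhizoma Recens (fresh ginger), Zingiberis Rhizoma (dried ginger), Pinelliae Tuber, Scutellariae Radix, Coptidis Rhizoma and Zizyphi Fructus. Most were given at 500 (high), 100 (medium) and 20 (low) µg/mL. Coptidis Rhizoma was given at 56 (medium) and 11.2 (low) µg/mL, since the series text set lower doses for extracts whose IC20 lay below 500 µg/mL. The control was the solvent DMSO (vehicle), which the sample labels give as 0.1% and the series text as 2%.

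The 58 libraries formed 24 groups. The vehicle and most doses of Sayeok-tang, both gingers, Pinelliae Tuber and Scutellariae Radix had 3 libraries each. Each dose of Bojungikgi-tang and the high dose of dried ginger had 2, and each dose of Coptidis Rhizoma and Zizyphi Fructus had 1. The expected counts summed to 22143845 to 31859981 per library (24077535 to 26409029 in the vehicle), and 21118 to 22865 genes had reads in a library. The labels do not say whether replicates were separate cultures, so the p-values measure spread between samples, which may be technical. The label codes give the vehicle libraries a prefix of their own and give the extracts shared prefixes, the 2 formulas together, the gingers together, Pinelliae Tuber with Scutellariae Radix, and Coptidis Rhizoma with Zizyphi Fructus. The labels do not say what a prefix means. If it marks libraries handled together, here called a set, set and treatment cannot be told apart in comparisons with the vehicle, while high against low dose and extract against extract were compared within a set. The largest 3 principal components held 31.9, 6.9 and 5.1% of the variance. The replicates that differed most within their groups were replicate 3 of Scutellariae Radix low (chi-square per gene of 17.24 and 13.73 with the others, which had 3.4) and replicate 3 of dried ginger low (15.21 and 14.28, against 2.33). The Zizyphi Fructus low library lay at -12.75 on component 4, where its other doses lay at 0.89 and 3.12, and the Coptidis Rhizoma libraries lay at 15.4 and 24.26.

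Fold changes are log2 values from edgeR. Their standard error (SE) was derived from the quasi-likelihood test, as the absolute fold change over the square root of F. It rests on the spread over all groups and not only on the groups compared. For groups of 1 library it holds no replicate spread of that group. Levels are CPM (counts divided by the scaled library total) with the standard deviation (SD) over the replicates. Genes were called at an adjusted p below 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg over 13945 genes), and gene lists fixed before the data were examined were tested with camera. Of the 349 calls among 806 list tests, 230 held with an estimated correlation between genes. Where a list has 1 count, it was the same over all genes and adjusted over the list alone. Counts of metallothioneins are of the tested genes of that list, for which the zinc exporter gene SLC30A1 was listed too. Values are gene totals over all annotated exons, and positions are on GRCh38. CYP1A1 (ENSG00000140465) lies on chr15 from 74719542 to 74725610, HMGCS1 (ENSG00000112972) on chr5 from 43289395 to 43313512, MT1X (ENSG00000187193) on chr16 from 56682424 to 56684196 and ASNS (ENSG00000070669) on chr7 from 97852118 to 97872542. IGFBP1 (ENSG00000146678) lies on chr7 from 45888357 to 45893668, CDKN1A (ENSG00000124762) on chr6 from 36676460 to 36687339 and HAMP (ENSG00000105697) on chr19 from 35280716 to 35285143. All are protein-coding genes.

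**Figure D1:**
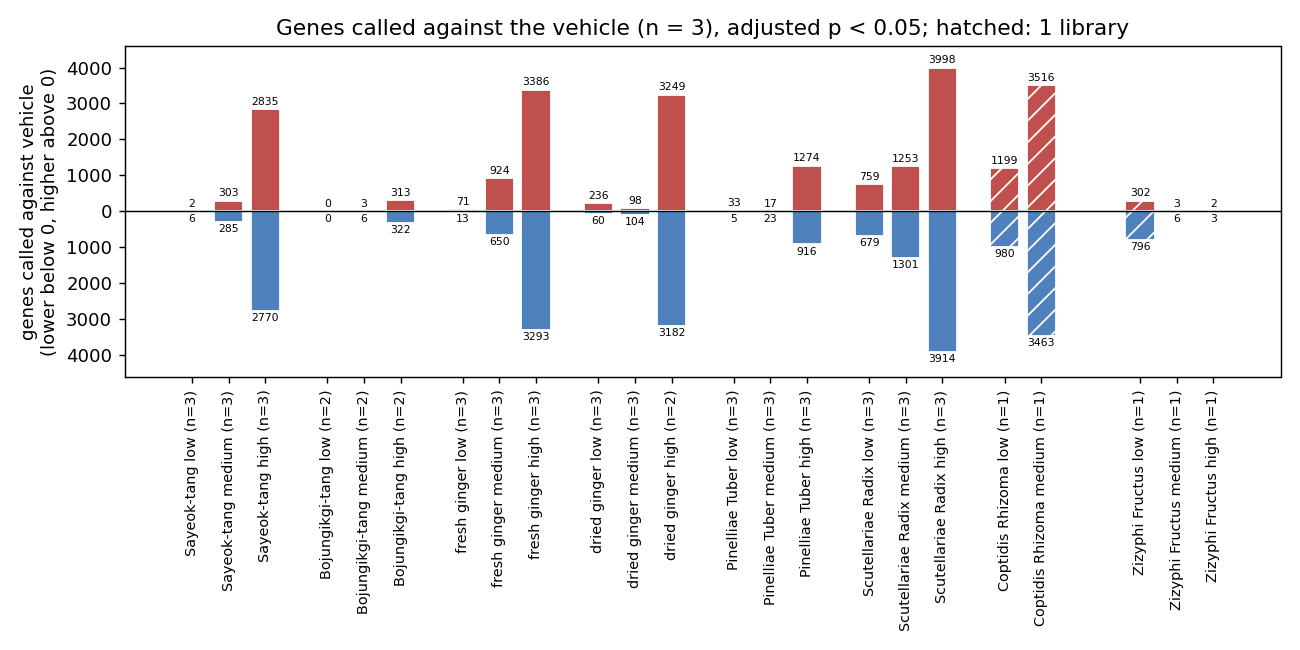
Genes called higher (above 0) and lower (below 0) than the vehicle (n = 3) for each extract and dose, with the number of libraries in brackets and hatched bars for groups of 1 library. Counts ran from 0 for Bojungikgi-tang low to 3998 higher and 3914 lower for Scutellariae Radix high.

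The comparisons with the vehicle asked which genes each extract changed at each dose. At the high dose of Sayeok-tang, CYP1A1, which encodes a xenobiotic-metabolising cytochrome P450 induced through the aryl hydrocarbon receptor (AhR), rose from 12.5 ± 1.7 to 293 ± 16 CPM (SD, n = 3 each). Metallothionein genes, which encode small metal-binding proteins, fell together. MT1G decreased by 3.46 ± 0.141 log2 units (SE) to 12.6 ± 2.1 CPM and MT1F by 3.41 ± 0.098. IGFBP1, a secreted binding protein for insulin-like growth factors, rose by 3.03 ± 0.117. Fibrinogen and other secreted plasma proteins were lower, with FGA at -1.19 ± 0.048, HP at -1.08 ± 0.046 and ALB at -0.36 ± 0.038. The cholesterol synthesis gene HMGCS1 fell from 475 ± 11 to 238 ± 4.3 CPM (-1 ± 0.039).

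By list, 6 of the 8 AhR targets rose, and all 8 metallothioneins and 21 of the 22 genes of cholesterol synthesis and uptake fell (camera, adjusted p of 2.8e-16, 1.2e-42 and 3.9e-35). Of the 19 targets of the oxidative stress regulator NRF2, 18 rose and 1 fell, including AKR1B10 (1.85 ± 0.054), GCLM (1.28 ± 0.06) and TXNRD1 (1.05 ± 0.037). Hypoxia and glycolysis genes rose in 20 of 22 (21 adjusted over the list alone), among them PDK1 (0.83 ± 0.077), and immediate early and SRF or YAP targets in 15 of 16, among them CCN1 (1.35 ± 0.064). Plasma protein genes fell in 15 of 22 and rose in 1, and the nuclear bile acid receptor gene NR1H4 decreased by 1.27 ± 0.05. Mitosis genes fell in 8 of 20 (9 adjusted over the list alone), a list call lost with an estimated correlation (adjusted p = 0.39). In all, 2835 genes were higher and 2770 lower, 280 of them by at least 2-fold.

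At the medium dose of Sayeok-tang, CYP1A1 rose by 1.83 ± 0.097 to 44.3 ± 0.83 CPM (n = 3). All 8 tested genes of the metallothionein list fell again, MT1G by 1.34 ± 0.118 and MT2A by 1.16 ± 0.095. The chemokine gene CCL20 rose by 0.59 ± 0.09, while ASNS, the asparagine synthetase gene and a target of the stress regulator ATF4, fell by 0.28 ± 0.052. The amino acid and integrated stress targets of ATF4 and CHOP fell in 5 of 20 (6 adjusted over the list alone; adjusted p = 0.071 with an estimated correlation). Mitosis genes rose in 3 of 20, or 11 adjusted over the list alone. The test called 303 genes higher and 285 lower. Without vehicle replicate 3 this count was 217, without its own replicate 1 it was 323, without vehicle replicate 1 it was 337 and without its own replicate 2 it was 382.

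The low dose of Sayeok-tang differed from the vehicle in 8 genes, 2 higher and 6 lower. The aldo-keto reductase genes AKR1C1 (-0.31 ± 0.051) and AKR1C2 (-0.23 ± 0.047) fell, as did PEBP1 (-0.18 ± 0.038), and ACIN1 rose by 0.34 ± 0.057. No metallothionein gene was called over all genes, but 7 of 8 fell adjusted over the list alone, with a median of -0.24 (camera, adjusted p = 3.4e-10). CYP1A1 stood at 15.7 ± 1.1 against 12.5 ± 1.7 CPM, which did not pass the test (0.33 ± 0.112). The count was 26 in DESeq2, 159 with no filter (91 higher and 68 lower) and 2 with only the groups compared in the fit. It was 4, 2 and 3 without vehicle replicates 1, 2 and 3, and 1 and 5 without its own replicates 2 and 3.

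At the high dose of Bojungikgi-tang, CYP1A1 rose by 2.75 ± 0.099 to 84.2 ± 2.8 CPM (n = 2). Metallothioneins fell in 7 of 8 genes, with MT1G at -1.49 ± 0.137 and MT1F at -1.37 ± 0.092. HAMP, the gene of the iron hormone hepcidin, fell from 65.1 ± 4.3 to 34.7 ± 5.6 CPM (-0.91 ± 0.092). AKR1B10 rose by 0.69 ± 0.06, NQO1 by 0.37 ± 0.043 and the growth factor gene AREG by 0.78 ± 0.107. NRF2 targets rose in 10 of 19 (12 up and 1 down adjusted over the list alone), and 14 of 22 cholesterol genes fell (16 adjusted over the list alone), HMGCS1 by 0.36 ± 0.043. ATF4 and CHOP targets fell in 8 of 20 and rose in 1 (10 and 1 adjusted over the list alone), with ASNS at -0.45 ± 0.06. Respiratory chain genes of the mitochondrial DNA rose in 9 of 13 (12 adjusted over the list alone), but their replicates lay far apart, with MT-ATP8 at 642 ± 350 and MT-ND6 at 695 ± 260 CPM. The test called 313 genes higher and 322 lower. Without its own replicate 2 the count was 183, and without vehicle replicate 3 it was 389.

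Bojungikgi-tang at its medium dose gave few calls, and CYP1A1 rose by 0.74 ± 0.117, while ASNS (-0.5 ± 0.06), the glycine transporter gene SLC6A9 (-0.47 ± 0.074) and MT1X (-0.48 ± 0.087) fell. Of the ATF4 and CHOP targets, 1 of 20 fell over all genes and 10 adjusted over the list alone, and for the metallothioneins these counts were 1 and 6 of 8. The test called 3 genes higher and 6 lower, against 2 and 7 with RLE scaling, 18 and 16 with only the groups compared in the fit and 2 and 16 without 3 libraries of other groups, an alternative chosen after seeing the data. The count was 1 and 3 without its own replicates 2 and 3, and 23 and 3 without vehicle replicates 2 and 3. The low dose gave 0 called genes in edgeR, 844 at an unadjusted p below 0.05, and 2 in DESeq2. With no filter on low counts edgeR called many more at this dose, as given below. Adjusted over the list alone, 5 of 8 metallothioneins were lower, with a median of -0.26 (camera, adjusted p = 3.3e-08).

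Fresh ginger at the high dose raised IGFBP1 by 4.4 ± 0.12 to 893 ± 24 CPM (n = 3). The immediate early transcription factor genes FOS (3.89 ± 0.19), FOSB (3.46 ± 0.237) and EGR1 (2.34 ± 0.076) rose, and CA9, a carbonic anhydrase gene induced by low oxygen, rose by 4.04 ± 0.343 from a low level of 0.433 CPM. CDKN1A, which encodes the cell cycle inhibitor p21, rose from 102 ± 0.81 to 224 ± 5.2 CPM. CYP1A1 rose by 1.98 ± 0.096. NR1H4 fell by 1.74 ± 0.052, FGA by 1.62 ± 0.048 and MT1F by 2.87 ± 0.093.

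Hypoxia and glycolysis genes rose in 21 of 22, including PFKFB3 (1.95 ± 0.117) and NDRG1 (1.87 ± 0.08). Immediate early and SRF or YAP targets rose in 15 of 16 and p53 targets in 13 of 17, with 3 of the latter lower. All 20 mitosis genes fell, KIF20A by 0.87 ± 0.041 and PLK1 by 0.61 ± 0.042, and 15 of 20 DNA replication genes fell while 2 rose. ATF4 and CHOP targets rose in 15 of 20 and fell in 3 (16 and 3 adjusted over the list alone), with GDF15 at 2.25 ± 0.065 and ASNS at 0.73 ± 0.049. NRF2 targets rose in 17 of 19 and fell in 1 (18 and 1 adjusted over the list alone). Cholesterol genes fell in 21 of 22 and rose in 1. Autophagy and lysosome genes rose in 15 of 20, SQSTM1 by 1.32 ± 0.036. Heat shock genes fell in 8 of 12 (8 down and 1 up adjusted over the list alone), a list call lost with an estimated correlation (adjusted p = 0.13). NF-kB and acute phase genes rose in 7 of 11 and fell in 4, among them CCL20 (2.33 ± 0.083) and FGB (-1.14 ± 0.055), and that list call was also lost (adjusted p = 0.17 with an estimated correlation). In all, 3386 genes were higher and 3293 lower, 482 by at least 2-fold.

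At the medium dose of fresh ginger, IGFBP1 (2.34 ± 0.116) and LCN15 (3.2 ± 0.173) rose. Metallothioneins fell in 8 of 8, MT1G by 2.16 ± 0.126, and hypoxia genes rose in 20 of 22 (21 adjusted over the list alone; camera, adjusted p = 6.9e-43), PDK1 by 0.92 ± 0.077. Cholesterol genes fell in 14 of 22 and rose in 1 (17 and 1 adjusted over the list alone). Mitosis genes fell in 8 of 20 (10 adjusted over the list alone; adjusted p = 0.16 with an estimated correlation), and plasma protein genes fell in 7 of 22 and rose in 3 (8 and 4 adjusted over the list alone; adjusted p = 0.27 with an estimated correlation). CYP1A1 rose by 0.39 ± 0.111. The test called 924 genes higher and 650 lower.

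With the low dose of fresh ginger, IGFBP1 (0.89 ± 0.119) and the glycolytic regulator gene PFKFB4 (0.76 ± 0.092) rose, and ASNS (-0.42 ± 0.052) and CDKN1A (-0.25 ± 0.036) fell. Hypoxia genes rose in 7 of 22 (14 up and 1 down adjusted over the list alone), and ATF4 and CHOP targets fell in 1 of 20 (10 down and 2 up adjusted over the list alone). The test called 71 genes higher and 13 lower, against 64 and 29 with RLE scaling. The count was 270 with only the groups compared in the fit, 307 with no filter, 26 and 45 without vehicle replicates 1 and 2, and 17 and 43 without its own replicates 2 and 3.

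Dried ginger at the high dose raised CYP1A1 by 4.24 ± 0.094 to 236 ± 13 CPM and AQP3, which encodes a water and glycerol channel, by 3.99 ± 0.091 to 63.2 ± 0.66 CPM (n = 2). IGFBP1 rose by 3.05 ± 0.123, AKR1B10 by 2.4 ± 0.058 and SLC7A11, the cystine transporter gene, by 2.24 ± 0.06. ASNS rose from 43.8 ± 1.4 to 122 ± 8.3 CPM. Fatty acid oxidation gene CPT1A rose by 1.46 ± 0.066 and the exporter gene ABCC2 by 1.62 ± 0.05. MT1F fell by 2.77 ± 0.109, the ubiquitin-like gene UBD by 1.95 ± 0.128 and the sodium channel gene SCN1A by 1.99 ± 0.078.

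All 19 NRF2 targets rose, and ATF4 and CHOP targets rose in 19 of 20 (20 adjusted over the list alone). Mitosis genes fell in 20 of 20, KIF20A by 1.34 ± 0.05 and PLK1 by 1.05 ± 0.05, and DNA replication genes fell in 16 of 20 and rose in 1. AhR targets rose in 7 of 8 (7 up and 1 down adjusted over the list alone), and targets of the drug receptors PXR and CAR rose in 5 of 11 and fell in 3 (camera, adjusted p = 0.00044). Autophagy and lysosome genes rose in 18 of 20, with SQSTM1 at 1.68 ± 0.039 and CTSL at 1 ± 0.053. Cholesterol genes fell in 20 of 22 and rose in 1. PPARA and fatty acid oxidation genes were split, 7 higher and 6 lower of 17 (8 and 7 adjusted over the list alone), with a median of -0.03 but a mean of 0.24 and a test pointing up (adjusted p = 0.013, and 0.077 as adjusted p with an estimated correlation). Hypoxia genes rose in 14 of 22, a list call lost with an estimated correlation (adjusted p = 0.21). The test called 3249 genes higher and 3182 lower, 515 by at least 2-fold.

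The medium dose of dried ginger lowered metallothioneins in 6 of 8 (7 adjusted over the list alone), MT1G by 0.82 ± 0.114 and MT2A by 0.73 ± 0.094, and raised CYP1A1 by 0.68 ± 0.106 and the sterol transporter gene ABCG5 by 0.45 ± 0.115. The test called 98 genes higher and 104 lower, and 397 in all with no filter. It called 126 higher and 207 lower without 3 libraries of other groups, an alternative chosen after seeing the data. Without vehicle replicates 1 and 3 the count was 95 and 51, and without its own replicates 1, 2 and 3 it was 97, 106 and 109. At the low dose, metallothioneins fell in 6 of 8, MT1E by 0.51 ± 0.087 and MT2A by 0.46 ± 0.093, and CDKN1A fell by 0.23 ± 0.036. Fatty acid synthesis and LXR targets rose in 3 of 14 (9 adjusted over the list alone). Ribosomal protein genes had 0 of 30 called in edgeR, a list call lost with an estimated correlation (adjusted p = 0.43). The low dose had 236 genes higher and 60 lower. With only the groups compared in the fit, 13 genes were called at the low and 284 at the medium dose, and with a GC content and length trend taken out, an alternative chosen after seeing the data, the low dose had 192 higher and 136 lower. The low count was 32 and 47 without vehicle replicates 1 and 3, 33 without its own replicate 3, which differed from its other replicates, and 542 and 460 without its own replicates 2 and 1.

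**Figure D2:**
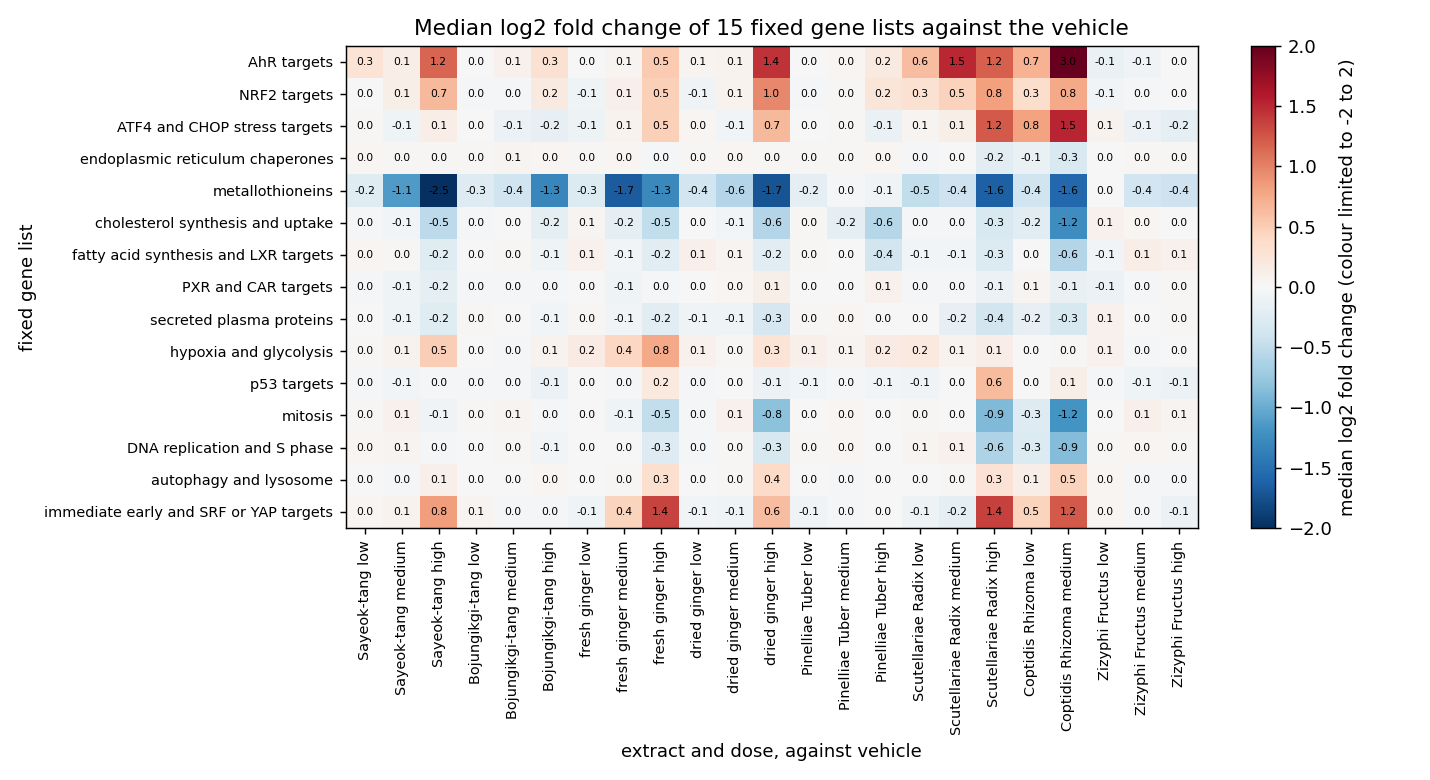
Median log2 fold change against the vehicle of 15 fixed gene lists (lines) in each extract and dose (columns), with colour limited to the range from -2 to 2. Metallothionein medians reached -2.55 at Sayeok-tang high, and AhR target medians reached 2.97 at Coptidis Rhizoma medium.

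Pinelliae Tuber at the high dose lowered the genes of cholesterol synthesis. MVD fell from 191 ± 0.58 to 96.6 ± 5.3 CPM (n = 3 each), HMGCS1 by 0.88 ± 0.039 and FDFT1 by 0.76 ± 0.04. Of the fatty acid genes, the acetyl-CoA synthetase gene ACSS2 fell by 0.94 ± 0.037 and the desaturase gene FADS2 by 0.76 ± 0.038. CYP1A1 rose by 1.95 ± 0.096 to 48.2 ± 1.7 CPM, AKR1B10 by 0.67 ± 0.054 and AREG by 0.68 ± 0.096. MT1X stood at 70.5 ± 5.8 against 68.3 ± 4.7 CPM and did not pass the test (0.05 ± 0.075).

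Cholesterol genes fell in 21 of 22 (camera, adjusted p = 4.5e-148), and fatty acid synthesis and LXR targets in 11 of 14 (12 adjusted over the list alone). NRF2 targets rose in 11 of 19 and fell in 1 (14 and 2 adjusted over the list alone). ATF4 and CHOP targets fell in 7 of 20 and rose in 2 (7 and 3 adjusted over the list alone; adjusted p = 0.067 with an estimated correlation), with ASNS at -0.36 ± 0.052. Hypoxia genes rose in 14 of 22 and fell in 2 (15 and 2 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). CDKN1A fell by 0.4 ± 0.036. The test called 1274 genes higher and 916 lower. Without vehicle replicate 3 the count was 1329.

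At the medium dose of Pinelliae Tuber, HMGCS1 (-0.28 ± 0.038), ACSS2 (-0.34 ± 0.036) and LPIN1, a gene of glycerolipid synthesis (-0.37 ± 0.042), fell, and CCL20 rose by 0.64 ± 0.088. Cholesterol genes fell in 8 of 22, or 19 adjusted over the list alone (camera, adjusted p = 5.8e-40). The test called 17 genes higher and 23 lower, against 15 and 32 with RLE scaling and 192 and 112 with no filter. The count was 120 with only the groups compared in the fit, 20 without vehicle replicate 1, and 14 and 16 without its own replicates 1 and 2. At the low dose, IGFBP1 (0.63 ± 0.121) and ZBED6 (0.67 ± 0.097) rose, and CDKN1A (-0.27 ± 0.036) and SESN2 (-0.24 ± 0.055) fell. Of the p53 targets, 1 of 17 fell (3 down and 1 up adjusted over the list alone). The test called 33 genes higher and 5 lower, against 72 and 44 in DESeq2, 71 and 38 with only the groups compared in the fit and 192 and 120 with no filter. The count was 2, 89 and 23 without vehicle replicates 1, 2 and 3, and 6 and 12 without its own replicates 1 and 2. With the replicate number as a block it was 72.

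Scutellariae Radix at the high dose gave the most called genes of the 6 replicated extracts, 3998 higher and 3914 lower, with 691 changed by at least 2-fold. CYP1A1 rose by 5.24 ± 0.09 to 470 ± 14 CPM, AQP3 by 5.2 ± 0.083 to 146 ± 6.7 CPM and IGFBP1 by 4.54 ± 0.121 to 984 ± 35 CPM (n = 3). The matrix protease gene MMP3 rose by 5.74 ± 0.156, the secreted peptide gene VGF by 4.74 ± 0.104 and the phosphatase gene DUSP5 by 3.95 ± 0.086. HSPA6, a heat-inducible chaperone gene, stood at 13.6 ± 0.72 CPM against 0.0412 CPM in the vehicle. HAMP fell by 3.68 ± 0.108 to 5.06 ± 0.3 CPM. CDKN1A rose by 2.15 ± 0.035 to 455 ± 15 CPM, ASNS by 1.86 ± 0.047 to 159 ± 5.7 CPM and the stress transcription factor gene DDIT3 (CHOP) by 0.95 ± 0.073.

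ATF4 and CHOP targets rose in 19 of 20, with ATF3 at 2.93 ± 0.085 and PPP1R15A at 2.72 ± 0.067, while endoplasmic reticulum chaperone genes fell in 12 of 16 and rose in 2 (13 and 2 adjusted over the list alone), CALR by 0.6 ± 0.032. All 20 mitosis genes and all 20 DNA replication genes fell, including MKI67 (-1.08 ± 0.069) and MCM5 (-0.99 ± 0.049). Targets of p53 rose in 16 of 17, with BBC3 at 1.37 ± 0.099. All 19 NRF2 targets rose, SLC7A11 by 2.5 ± 0.056, and AhR targets rose in 7 of 8. Plasma protein genes fell in 19 of 22 and rose in 2, APOH by 1.12 ± 0.057, and bile acid and FXR genes fell in 6 of 9, NR1H4 by 1.58 ± 0.051. Fatty acid synthesis genes fell in 11 of 14 and rose in 1, a list call lost with an estimated correlation (adjusted p = 0.06), as were those of NF-kB and acute phase (4 up and 6 down of 11, adjusted p = 0.15) and ribosomal proteins (24 up of 30, 25 adjusted over the list alone, adjusted p = 0.7). SRF and immediate early targets rose in 14 of 16 and fell in 2, EGR1 by 2.87 ± 0.075.

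Scutellariae Radix at its medium dose raised CYP1A1, which rose by 5.77 ± 0.09 to 681 ± 26 CPM (n = 3), a higher mean than at the high dose. SOS1, which encodes an exchange factor for Ras, rose by 1.85 ± 0.048 to 321 ± 14 CPM. AhR targets rose in 6 of 8 (camera, adjusted p = 1.2e-52) and NRF2 targets in 17 of 19, among them AKR1B10 (1.05 ± 0.054), GCLM (1.02 ± 0.061) and NQO1 (0.81 ± 0.039), and HMOX1, the heme oxygenase gene, rose by 0.6 ± 0.05. CDKN1A stood at 102 ± 1.8 against 102 ± 0.81 CPM and did not pass the test. The transporter gene SLC6A12 (-1.43 ± 0.118) and the growth factor receptor gene PDGFRB (-1.28 ± 0.103) fell. Plasma protein genes fell in 13 of 22 and rose in 1 (15 and 1 adjusted over the list alone), TTR by 0.44 ± 0.074, and 4 of 14 circadian clock genes fell. The test called 1253 genes higher and 1301 lower.

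With the low dose of Scutellariae Radix, CYP1A1 still rose by 4.25 ± 0.089 to 237 ± 33 CPM (n = 3). AKR1B10 rose by 0.82 ± 0.054, NQO1 by 0.59 ± 0.039 and IGFBP1 by 0.89 ± 0.119, while EGR1 (-0.56 ± 0.092) and CDKN1A (-0.32 ± 0.036) fell. AhR targets rose in 4 of 8 (5 adjusted over the list alone) and NRF2 targets in 14 of 19 (16 up and 1 down adjusted over the list alone). SRF and immediate early targets fell in 5 of 16 (6 adjusted over the list alone) and p53 targets in 4 of 17 (6 adjusted over the list alone). Ribosomal protein genes rose in 10 of 30 (16 adjusted over the list alone), a list call lost with an estimated correlation (adjusted p = 0.27). The listed genes held 2.08, 2.11 and 2.43% of the counts in replicates 1, 2 and 3, against 1.96 to 2.09% in the vehicle. Replicate 3 carried a trend with transcript length (medians of 0.103 among the shortest and -0.085 among the longest 20% of genes). This list rise is therefore not read as an effect of the dose. The test called 759 genes higher and 679 lower. The count was 297 with only the groups compared in the fit, 591 without its own replicate 3, which differed from its other replicates, and 900 and 847 without vehicle replicates 2 and 3.

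The Coptidis Rhizoma and Zizyphi Fructus groups had no replicates. Their counts used the spread pooled from the other groups, and their lists were placed among 10000 random lists of genes matched in level. The random genes were drawn independently, so the percentile does not allow for list genes that vary together. It ranks a shift and does not measure its size. In the Zizyphi Fructus high library, the p53 list lay at percentile 0 with a median of -0.11. In the Coptidis Rhizoma medium library, CYP1A1 stood at 1140 CPM against 12.5 ± 1.7 in the vehicle, AQP3 at 144 against 3.98 ± 0.35 and IGFBP1 at 1430 against 42.2 ± 3.8 CPM. HMGCS1 stood at 160 against 475 ± 11 and the glutathione transferase gene GSTA1 at 13.3 against 79.6 ± 3.1 CPM. ASNS stood at 240 CPM (2.45 ± 0.059) and DDIT3 at 30.4 CPM (1.3 ± 0.097), while HMOX1 was lower than the vehicle at 34.6 CPM (-0.77 ± 0.081), unlike most NRF2 targets, of which 15 of 19 were called higher and 2 lower (median 0.75, percentile 100). By the pooled spread, 3516 genes were called higher and 3463 lower, 1079 by at least 2-fold.

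AhR targets were called higher in 8 of 8 (median 2.97, percentile 100) and ATF4 and CHOP targets in 18 of 20 (20 adjusted over the list alone; median 1.52, percentile 100). Cholesterol genes were called lower in 21 of 22 (21 down and 1 up adjusted over the list alone; median -1.24, percentile 0), and mitosis genes in 20 of 20, KIF20A at 20.7 against 76.7 CPM. Endoplasmic reticulum chaperone genes were called lower in 12 of 16 and higher in 2 (median -0.3). Genes of gluconeogenesis and FOXO1 targets were called higher in 5 of 8 and lower in 1 (median 0.68). Metallothioneins were called lower in 5 of 8 and higher in 1. In the low-dose library, CYP1A1 stood at 108 CPM, SLC7A11 at 135 against 49.9 ± 2 and ASNS at 103 CPM, and 17 of 20 ATF4 and CHOP targets were called higher and 14 of 20 mitosis genes lower (18 and 15 adjusted over the list alone). The mitochondrial ribosomal RNA MT-RNR2 stood at 112000 against 20600 ± 360 CPM and MT-RNR1 at 53600 against 4930 ± 390. Of the 13 respiratory chain genes of the mitochondrial DNA, 5 were called higher and 6 lower (5 and 7 adjusted over the list alone), with MT-ND5 at 8480 against 3510 ± 83 and MT-ND4 at 5050 against 10100 ± 1400 CPM. The low library had 1199 genes called higher and 980 lower.

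The Zizyphi Fructus libraries differed less from the vehicle. At the high and medium doses, ASNS stood at 31.2 and 29.4 CPM against 43.8 ± 1.4, and CYP1A1 was not among the called genes. At the high dose, 1 of 20 ATF4 and CHOP targets was called lower (7 down and 1 up adjusted over the list alone; median -0.18, percentile 0), and 6 of 8 metallothioneins were lower adjusted over the list alone, against 0 over all genes in edgeR. By the pooled spread, 2 genes were higher and 3 lower at the high dose, against 1 and 3 with RLE scaling and 35 and 17 with only the groups compared in the fit. The medium dose had 3 higher and 6 lower, against 20 and 14 in DESeq2 and 40 and 30 with only the groups compared. Without vehicle replicate 3 the counts of the high and medium doses were 2 and 1, and at the medium dose the count was 2 and 38 without vehicle replicates 1 and 2. In the low-dose library, 302 genes were called higher and 796 lower, and 351 and 456 with the GC content and length trend taken out. There the transcription factor gene CEBPB stood at 63.1 against 27.2 ± 2.9 CPM and the proliferation marker gene MKI67 at 204 against 329 ± 8.9. The mitosis list of that library had a median of -0.01 (percentile 50.13). The library carried a trend with GC content and transcript length, given below, so these 2 values are not read as specific to the genes. Without vehicle replicate 2 the count of the low dose was 558.

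**Figure D3:**
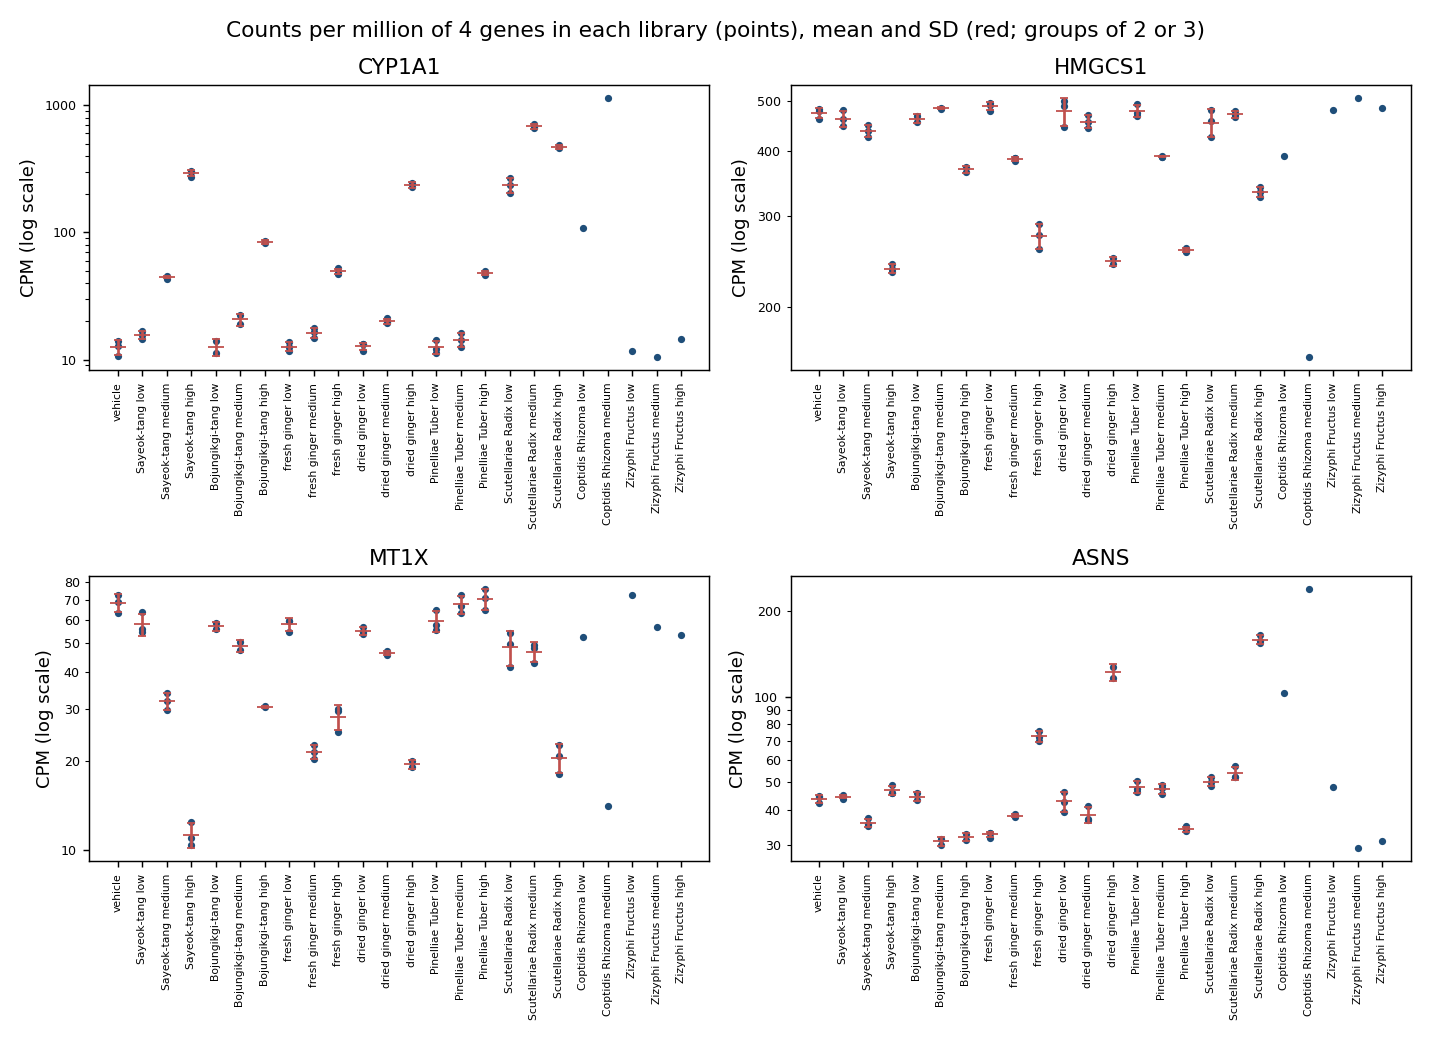
Level of CYP1A1, HMGCS1, MT1X and ASNS in every library (points, CPM on a log axis) for the vehicle and each extract and dose, with the group mean and SD. CYP1A1 lay between 10.8 and 14 CPM in the vehicle libraries and at 1140 CPM in the Coptidis Rhizoma medium library.

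High against low dose asked what changed with dose inside a library set, without the vehicle libraries. With Sayeok-tang, CYP1A1 rose from 15.7 ± 1.1 at the low to 293 ± 16 CPM at the high dose (4.22 ± 0.087), IGFBP1 by 2.92 ± 0.116, and MT1F fell by 3.2 ± 0.1. All 8 metallothioneins fell, NRF2 targets rose in 17 of 19 and fell in 1 (18 and 1 adjusted over the list alone), and plasma protein genes fell in 17 of 22 and rose in 1 (18 and 1 adjusted over the list alone). With Bojungikgi-tang, CYP1A1 rose by 2.74 ± 0.113, HAMP fell by 0.99 ± 0.099 and ASNS by 0.47 ± 0.065. Metallothioneins fell in 7 of 8 and cholesterol genes in 7 of 22 (20 adjusted over the list alone). The mitochondrial DNA list, with 2 of 13 genes higher (7 adjusted over the list alone), lost its call with an estimated correlation (adjusted p = 0.079). Sayeok-tang had 2563 genes higher and 2687 lower at the high dose. Bojungikgi-tang had 113 and 122, a count that was 79 with only the groups compared in the fit, 393 with no filter, 81 without high replicate 2, 83 and 141 without low replicates 3 and 2.

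With fresh ginger, FOS rose by 4.1 ± 0.193, IGFBP1 by 3.51 ± 0.113 and CDKN1A by 1.38 ± 0.035 from the low to the high dose, and NR1H4 fell by 1.83 ± 0.052. All 16 SRF and immediate early targets and 21 of 22 hypoxia genes rose, and all 20 mitosis genes fell. With dried ginger, CYP1A1 rose by 4.21 ± 0.092, AQP3 by 4.04 ± 0.089 and ASNS by 1.51 ± 0.052, and all 19 NRF2 targets and 19 of 20 autophagy and lysosome genes rose. Fresh ginger had 3251 genes higher and 3384 lower, and dried ginger 3231 and 3383.

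With Pinelliae Tuber, HMGCS1 fell from 479 ± 13 at the low to 258 ± 2.5 CPM at the high dose and MVD by 0.98 ± 0.073, and CYP1A1 rose by 1.94 ± 0.096. Cholesterol genes fell in 21 of 22 (camera, adjusted p = 2e-183), fatty acid synthesis genes in 10 of 14 (13 adjusted over the list alone) and ATF4 and CHOP targets in 7 of 20 with 1 higher (7 and 4 adjusted over the list alone). The count was 710 higher and 694 lower, and it was 921 and 931 without low replicates 2 and 3 and 924 without high replicate 1. With Scutellariae Radix, CYP1A1 rose by only 0.99 ± 0.067 between the low and high doses, while CDKN1A rose by 2.47 ± 0.035, ASNS by 1.66 ± 0.047 and EGR1 by 3.43 ± 0.079, and HAMP fell by 3.98 ± 0.106 from 79.8 ± 6.5 CPM. ATF4 and CHOP targets rose in 18 of 20 and fell in 1, p53 targets rose in 16 of 17 (17 adjusted over the list alone), and all 20 DNA replication genes fell. Metallothioneins fell in 6 of 8, a list call lost with an estimated correlation (adjusted p = 0.12), as was that of the replication-dependent histones (5 of 9 higher, adjusted p = 0.11). There were 3799 genes higher and 3972 lower.

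Fresh against dried ginger asked how 2 preparations of the same rhizome differed at equal doses in 1 library set. At the high dose, CYP1A1 was lower with fresh ginger, 49.3 ± 2.5 (n = 3) against 236 ± 13 CPM (n = 2). FOS (2.81 ± 0.198), FOSB (3.17 ± 0.272), UBD (2.41 ± 0.124), IGFBP1 (1.35 ± 0.117) and CDKN1A (0.99 ± 0.039) were higher with fresh ginger, and GSTA2 (-1.43 ± 0.108) and ASNS (-0.75 ± 0.05) lower. All 22 hypoxia genes, all 20 mitosis genes and 15 of 17 p53 targets were higher with fresh ginger, and 16 of 19 NRF2 targets and 8 of 11 PXR and CAR targets were lower. AhR targets were lower in 4 of 8 (6 adjusted over the list alone), and plasma protein genes were higher in 8 of 22 and lower in 3 (9 and 4 adjusted over the list alone; adjusted p = 0.35 with an estimated correlation). The test called 1846 genes higher and 1427 lower, and 1735 in all with only the groups compared in the fit. Without dried ginger high replicates 1 and 2, the count was 2170 and 2020.

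At the medium dose, LCN15 (2.42 ± 0.156) and IGFBP1 (2.2 ± 0.114) were higher with fresh ginger and MT1F lower (-1.62 ± 0.089). Hypoxia genes were higher in 21 of 22 (22 adjusted over the list alone), metallothioneins lower in 8 of 8 and mitosis genes lower in 12 of 20 (17 adjusted over the list alone), the opposite direction of the high dose for mitosis. The count was 601 higher and 397 lower, and it was 657 without fresh ginger replicate 1. At the low dose, APOC3 was higher (0.35 ± 0.07) and SLC7A11 (-0.4 ± 0.059), ASNS (-0.38 ± 0.052), MARS1 (-0.2 ± 0.031) and YARS1 (-0.15 ± 0.03) were lower with fresh ginger. The ATF4 and CHOP list was lower in 2 of 20 (9 adjusted over the list alone). With only the groups compared in the fit, edgeR called 0 genes, so none of these calls was made there, and DESeq2 called 14. This count of 5 genes was 3 without fresh ginger replicate 3, and 29 and 3 without dried ginger replicates 2 and 3. It was 293 with no filter (150 higher and 143 lower) and 10 with the replicate number as a block (4 higher and 6 lower).

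Bojungikgi-tang against Sayeok-tang compared the water extracts of the formulas. At the high dose, IGFBP1 stood at 60.6 ± 1.6 (n = 2) against 345 ± 11 CPM (n = 3), CYP1A1 (-1.8 ± 0.083) was lower, and MT1F (2.04 ± 0.118), FGA (1.24 ± 0.052), NR1H4 (1.05 ± 0.055) and HMGCS1 (0.64 ± 0.043) were higher with Bojungikgi-tang. NRF2 targets were lower in 18 of 19, SRF and immediate early targets in 15 of 16 and hypoxia genes in 19 of 22, and cholesterol genes were higher in 20 of 22 and lower in 1. Metallothioneins were higher in 6 of 8 (7 adjusted over the list alone) and plasma protein genes in 12 of 22 (13 adjusted over the list alone). The mitochondrial DNA list was higher in 8 of 13 genes (9 adjusted over the list alone; adjusted p = 0.43 with an estimated correlation). The test called 1811 genes higher and 1845 lower, and the count was 2099 without Bojungikgi-tang high replicate 2. At the medium dose, MT1G (0.91 ± 0.131) was higher and CYP1A1 (-1.09 ± 0.102) and AKR1B10 (-0.45 ± 0.062) lower. Metallothioneins were higher in 7 of 8 (8 adjusted over the list alone). The medium count was 28 higher and 16 lower, against 25 and 24 in DESeq2, 16 and 22 with only the groups compared in the fit and 65 and 91 with no filter. It was 15 and 7 without Bojungikgi-tang replicates 2 and 3, and 25 and 14 without Sayeok-tang replicates 2 and 3. At the low dose edgeR called 0 genes, 482 had an unadjusted p below 0.05, and DESeq2 called 0. With no filter on low counts edgeR did call genes in this comparison, as given below.

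Pinelliae Tuber against Scutellariae Radix at the high dose gave the most called genes of the 3 pairs of extracts compared, 4007 genes higher and 3788 lower. HAMP stood at 67.5 ± 7.2 against 5.06 ± 0.3 CPM and MT1X at 70.5 ± 5.8 against 20.5 ± 2.3 CPM (n = 3 each). CYP1A1 (-3.29 ± 0.076), ASNS (-2.22 ± 0.048) and CDKN1A (-2.56 ± 0.036) were lower with Pinelliae Tuber. All 20 mitosis and all 20 DNA replication genes and 13 of 16 endoplasmic reticulum chaperone genes were higher with Pinelliae Tuber, with 2 chaperone genes lower. Of the ATF4 and CHOP targets, 19 of 20 were lower and 1 higher, p53 targets lower in 16 of 17 and cholesterol genes lower in 17 of 22 with 1 higher. Plasma protein genes were higher in 16 of 22 and lower in 2, a list call lost with an estimated correlation (adjusted p = 0.084), as was that of the histones (5 of 9 lower, adjusted p = 0.062).

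Across genes, the change from low to high dose correlated between extracts with no shared libraries. Pearson r was 0.61 for fresh with dried ginger and for dried ginger with Scutellariae Radix, 0.6 for Sayeok-tang with dried ginger, 0.56 for Sayeok-tang with fresh ginger and 0.09 for Pinelliae Tuber with Scutellariae Radix. These are correlations over 13945 genes, which are not independent replicates. Of the 4477 genes called in both gingers, 96.3% moved in the same direction, and of the 956 called in both Pinelliae Tuber and Scutellariae Radix 62.6% did. From the low to the high dose CYP1A1 rose in all 6 extracts that had replicates, by 0.99 to 4.22, and HMGCS1 fell in all 6, at -0.32 to -0.96, while in Scutellariae Radix the CYP1A1 mean was highest at the medium dose.

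**Figure D4:**
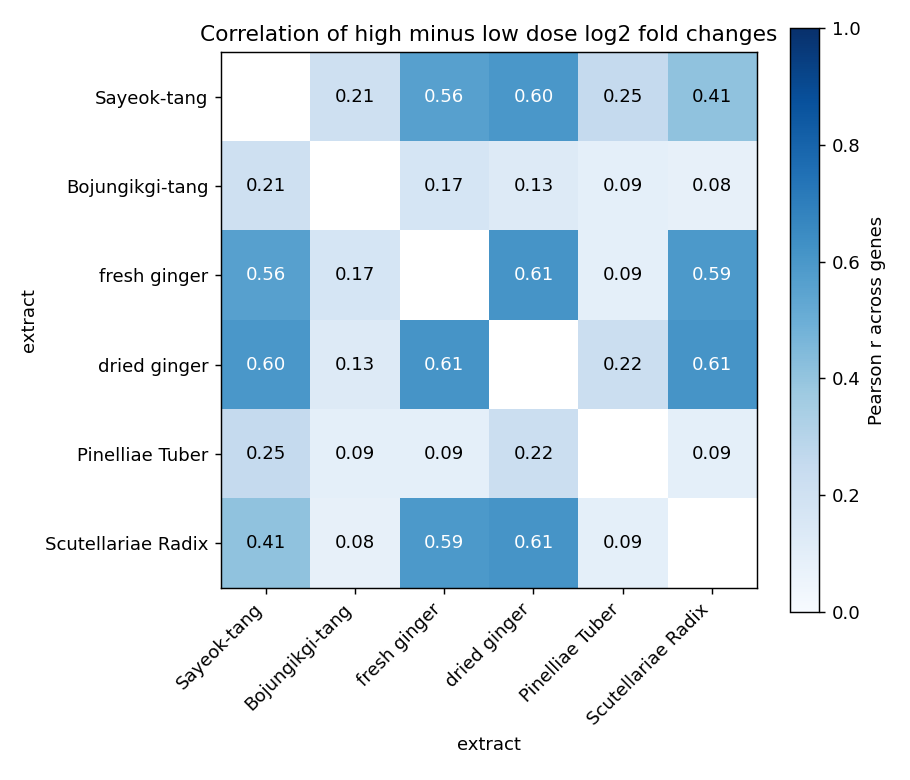
Pearson correlation across 13945 genes of the log2 fold change from low to high dose between the 6 extracts with replicates. The gingers, Sayeok-tang and Scutellariae Radix gave r between 0.41 and 0.61 with one another, and Bojungikgi-tang and Pinelliae Tuber gave 0.25 or less with any other extract. Among genes called in either extract, Sayeok-tang gave 0.51 with Bojungikgi-tang and 0.4 with Pinelliae Tuber, from 0.21 and 0.25, so this contrast depends on the genes included.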

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

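The tests of the library set and of a fall with dose were chosen only after the result was seen. Groups of 3 libraries or fewer are too small for a test of single samples, so no library is singled out by such a test here. The change from low to high dose was compared between extracts that share a label prefix (a set) by an interaction term (edgeR, adjusted by Benjamini-Hochberg). Between fresh and dried ginger, 2215 genes differed in that change, 1314 of them more positive with fresh ginger, and 167 were called in both gingers in opposite directions, such as UBD (0.41 and -1.75) and TXNIP (0.39 and -1.08). The p53 list pointed to fresh ginger (camera, adjusted p = 4e-18) and the NRF2 list to dried ginger (adjusted p = 3.5e-19). Between Bojungikgi-tang and Sayeok-tang, 1932 genes differed, 975 more positive with Bojungikgi-tang, and 12 were called in opposite directions, such as CYP24A1 (-0.31 and 1.11) and ANKRD1 (-0.52 and 0.64). Between Pinelliae Tuber and Scutellariae Radix, 6198 genes differed, 3198 more positive with Pinelliae Tuber, and 358 were called in opposite directions, such as EGR1 (-0.41 and 3.43), ATF3 (-0.36 and 2.74), CDKN1A (-0.13 and 2.47) and ASNS (-0.49 and 1.66).

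Metallothionein genes lay below the vehicle at the low dose of each extract with replicates, with list medians of -0.24, -0.26, -0.28, -0.39, -0.2 and -0.49 in Sayeok-tang, Bojungikgi-tang, fresh ginger, dried ginger, Pinelliae Tuber and Scutellariae Radix. Higher metallothionein in the vehicle libraries, which have a label prefix of their own, may account for this. It would shift Zizyphi Fructus too, whose medians were -0.42 at the high, -0.38 at the medium and -0.01 at the low dose, so the test did not decide. A fall with dose was seen from low to medium in 4 of 6 extracts, and the falls of Sayeok-tang, the gingers and Bojungikgi-tang at the high dose were also seen against the low dose, where the vehicle plays no part. For the low doses, vehicle and extract cannot be told apart, since no other vehicle libraries were used.

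Both Coptidis Rhizoma libraries had a high share of mitochondrial ribosomal RNA. MT-RNR2 held 8.27 and 9.82% of the counts of the medium and low libraries against 1.84 to 2.96% elsewhere. Smaller rises were seen in replicated groups. MT-RNR1 stood at 0.85 to 1.12% in Sayeok-tang high and 0.91 to 0.97% in fresh ginger high, against 0.47 to 0.55% in the vehicle. At their low doses it stood at 0.48 to 0.54% and 0.45 to 0.51%. At the high dose of the other replicated extracts it stood at 0.46 to 0.57%. The library set does not account for the high share in Coptidis Rhizoma, since the Zizyphi Fructus libraries of that set held at most 2.11% of MT-RNR2. Nor did these few genes drive the number of called genes, since 2197 were called at the low dose without the genes of the mitochondrial DNA, against 2179 with them. That fit does not show whether what raised these RNAs also moved nuclear genes. A larger share of RNA without poly(A) tails could not be judged, since 4 of 23 listed RNAs were measured, with medians of -0.5 in the medium and 0.27 in the low library. The extract itself, a biological explanation, was not tested, and 1 library per dose leaves it open, so a preparation of these RNA samples may also account for it.

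More genes were called at the low dose of Zizyphi Fructus (1098) than at its higher doses (5 and 9). GC content and transcript length went with 32.8% of the variance of this library's difference from the mean of the other doses. With that trend taken out, 807 genes were called at the low dose (351 higher and 456 lower, from 302 and 796). The high and medium doses then had 20 and 30. The same correction left 328 genes at dried ginger low (from 296), where the fit without its replicate 3 called 33. The correction may thus not remove such a library difference in full, so the test does not decide whether the trend was the whole cause. How many of the 807 were among the 1098 was not counted, and the fewer lower calls go with the trend as part of the cause. A trend shared with the replicates that differed most within their groups, replicate 3 of dried ginger low and replicate 3 of Scutellariae Radix low, was not decided by Pearson r across genes of -0.1 and 0.25, while GC content and length went with 46.4 and 37.3% of the variance of their differences from their own replicates. A preparation difference of this library may account for the pattern, and no biological explanation was tested.

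With 3 libraries against 3, the 10 splits of the libraries are too few for a share below 0.05. Fitted alone, the real split and the highest of the others called 5813 and 0 genes for Sayeok-tang high, 611 and 0 for its medium dose, 5780 and 0 for fresh ginger high, 1996 and 1 for its medium dose, 270 and 2 for its low dose, 284 and 5 for dried ginger medium, 13 and 3 for its low dose, 2265 and 1 for Pinelliae Tuber high, 120 and 6 for its medium dose, 109 and 1 for its low dose, 8182 and 0 for Scutellariae Radix high, 2583 and 3 for its medium dose and 297 and 0 for its low dose. In each of these the real split alone (1 of 10) reached its count. For Sayeok-tang low the real split called 2 genes and another 4, so 2 of 10 splits reached it. High against low gave 4820 and 0 for Sayeok-tang, 5824 and 0 for fresh ginger, 1363 and 2 for Pinelliae Tuber and 6903 and 0 for Scutellariae Radix. Fresh against dried ginger gave 1289 and 1 at the medium dose, and 0 and 1 at the low dose, where all 10 of 10 splits reached the real count. Pinelliae Tuber against Scutellariae Radix gave 7907 and 0.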

How the results depend on the processing

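The settings without 3 libraries (Zizyphi low, replicate 3 of dried ginger low and of Scutellariae low), with a GC content and length trend taken out, and without genes of the mitochondrial DNA were chosen after seeing the data. No named gene that was called in the main fit or under the setting turned direction. Turns of genes called in neither were not counted. Counts above 1500 called genes stayed within 1.5 times under other scaling (RLE), DESeq2, no filter and the replicate block. The comparisons with fewer than 300 called genes moved most often, and the cause was not tested, except that leaving out libraries also lowers their number. Groups left with 1 library were assumed to vary like the others. With an estimated correlation 230 list calls were left of 349. RLE and removal of the mitochondrial genes moved no count by 1.5 times. A replicate number as a block gave 72 for Pinelliae low, 3 for Zizyphi medium and 10 for fresh against dried ginger low called genes, and no other count moved by 1.5 times. The labels do not say that the numbers pair libraries, and they were not taken to, since not every pair with the same number correlated above 0.1 (lowest -0.18). The mean was 0.009 for the same and -0.004 for other numbers, and 0.052 and -0.028 for the formulas. In their own set 27 of 50 libraries lay closest to their own number, so pairing in part is not excluded. Different pseudocounts were not run, since the values are counts.

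Without these 3 libraries there were 15 for Sayeok-tang low, 18 for Bojungikgi-tang medium, 1 for Bojungikgi-tang low, 140 for fresh ginger low, 333 for dried ginger medium, 38 for dried ginger low, 85 for Pinelliae medium, 98 for Pinelliae low, 718 for Scutellariae low, 12 for Zizyphi high, 34 for Zizyphi medium and 3 for fresh against dried ginger low. With no filter on low counts there were 159 for Sayeok-tang low, 161 for Bojungikgi-tang medium, 145 for Bojungikgi-tang low, 307 for fresh ginger low, 397 for dried ginger medium, 798 for dried ginger low, 304 for Pinelliae medium, 312 for Pinelliae low, 175 for Zizyphi high, 253 for Zizyphi medium, 393 for Bojungikgi-tang high against low, 293 for fresh against dried ginger low, 156 for Bojungikgi-tang against Sayeok-tang medium and 88 for Bojungikgi-tang against Sayeok-tang low. DESeq2 called 26 for Sayeok-tang low, 24 for Bojungikgi-tang medium, 2 for Bojungikgi-tang low, 116 for Pinelliae low, 9 for Zizyphi high, 34 for Zizyphi medium and 14 for fresh against dried ginger low. With the GC content and length trend taken out there were 20 for Zizyphi high and 30 for Zizyphi medium. Fitting only the groups compared gave 2 for Sayeok-tang low, 34 for Bojungikgi-tang medium, 1 for Bojungikgi-tang low, 270 for fresh ginger low, 13 for dried ginger low, 120 for Pinelliae medium, 109 for Pinelliae low, 297 for Scutellariae low, 52 for Zizyphi high, 70 for Zizyphi medium, 79 for Bojungikgi-tang high against low, 1735 for fresh against dried ginger high and 0 for fresh against dried ginger low. The correlations of high minus low among genes called in either extract were 0.51 for Sayeok-tang and Bojungikgi-tang, 0.74 for Sayeok-tang and fresh ginger, 0.72 for Sayeok-tang and dried ginger, 0.4 for Sayeok-tang and Pinelliae, 0.36 for Bojungikgi-tang and fresh ginger, 0.32 for Bojungikgi-tang and dried ginger, 0.35 for Bojungikgi-tang and Pinelliae, 0.23 for Bojungikgi-tang and Scutellariae and 0.73 for fresh ginger and dried ginger. Among genes with a mean of at least 5 CPM they were 0.4 for Sayeok-tang and Bojungikgi-tang, 0.79 for Sayeok-tang and fresh ginger, 0.75 for Sayeok-tang and dried ginger, 0.44 for Sayeok-tang and Pinelliae, 0.51 for Sayeok-tang and Scutellariae, 0.33 for Bojungikgi-tang and fresh ginger, 0.32 for Bojungikgi-tang and dried ginger, 0.35 for Bojungikgi-tang and Pinelliae, 0.22 for Bojungikgi-tang and Scutellariae, 0.78 for fresh ginger and dried ginger, 0.27 for fresh ginger and Pinelliae and 0.72 for fresh ginger and Scutellariae.

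Leaving out each library in turn, counts lay at 217 to 497 for Sayeok-tang medium, 1 to 7 for Sayeok-tang low, 183 to 464 for Bojungikgi-tang high, 1 to 23 for Bojungikgi-tang medium, 17 to 70 for fresh ginger low, 51 to 232 for dried ginger medium, 32 to 542 for dried ginger low, 1329 to 1925 for Pinelliae high, 14 to 39 for Pinelliae medium, 2 to 89 for Pinelliae low, 591 to 1761 for Scutellariae low, 2 to 5 for Zizyphi high, 1 to 38 for Zizyphi medium, 558 to 1079 for Zizyphi low, 81 to 164 for Bojungikgi-tang high against low, 921 to 1073 for Pinelliae high against low, 2020 to 3028 for fresh against dried ginger high, 657 to 816 for fresh against dried ginger medium, 3 to 29 for fresh against dried ginger low, 2099 to 3291 for Bojungikgi-tang against Sayeok-tang high and 7 to 32 for Bojungikgi-tang against Sayeok-tang medium. Without vehicle replicate 1 it was 337 for Sayeok-tang medium, 4 for Sayeok-tang low, 26 for fresh ginger low, 95 for dried ginger medium, 32 for dried ginger low, 20 for Pinelliae medium, 2 for Pinelliae low and 2 for Zizyphi medium. Without vehicle replicate 2 it was 2 for Sayeok-tang low, 23 for Bojungikgi-tang medium, 45 for fresh ginger low, 89 for Pinelliae low, 900 for Scutellariae low, 38 for Zizyphi medium and 558 for Zizyphi low. Without vehicle replicate 3 it was 217 for Sayeok-tang medium, 3 for Sayeok-tang low, 389 for Bojungikgi-tang high, 3 for Bojungikgi-tang medium, 51 for dried ginger medium, 47 for dried ginger low, 1329 for Pinelliae high, 23 for Pinelliae low, 847 for Scutellariae low, 2 for Zizyphi high and 1 for Zizyphi medium. Other libraries moved these counts to the following values, Bojungikgi-tang high replicate 2: 183 (Bojungikgi-tang high), 81 (Bojungikgi-tang high against low) and 2099 (Bojungikgi-tang against Sayeok-tang high), Bojungikgi-tang low replicate 2: 141 (Bojungikgi-tang high against low), Bojungikgi-tang low replicate 3: 83 (Bojungikgi-tang high against low), Bojungikgi-tang medium replicate 2: 1 (Bojungikgi-tang medium) and 15 (Bojungikgi-tang against Sayeok-tang medium), Bojungikgi-tang medium replicate 3: 3 (Bojungikgi-tang medium) and 7 (Bojungikgi-tang against Sayeok-tang medium), Pinelliae high replicate 1: 924 (Pinelliae high against low), Pinelliae low replicate 1: 6 (Pinelliae low), Pinelliae low replicate 2: 12 (Pinelliae low) and 921 (Pinelliae high against low), Pinelliae low replicate 3: 931 (Pinelliae high against low), Pinelliae medium replicate 1: 14 (Pinelliae medium), Pinelliae medium replicate 2: 16 (Pinelliae medium), Sayeok-tang low replicate 2: 1 (Sayeok-tang low), Sayeok-tang low replicate 3: 5 (Sayeok-tang low), Sayeok-tang medium replicate 1: 323 (Sayeok-tang medium), Sayeok-tang medium replicate 2: 382 (Sayeok-tang medium) and 25 (Bojungikgi-tang against Sayeok-tang medium), Sayeok-tang medium replicate 3: 14 (Bojungikgi-tang against Sayeok-tang medium), Scutellariae low replicate 3: 591 (Scutellariae low), fresh ginger low replicate 2: 17 (fresh ginger low), fresh ginger low replicate 3: 43 (fresh ginger low) and 3 (fresh against dried ginger low), fresh ginger medium replicate 1: 657 (fresh against dried ginger medium), dried ginger high replicate 1: 2170 (fresh against dried ginger high), dried ginger high replicate 2: 2020 (fresh against dried ginger high), dried ginger low replicate 1: 460 (dried ginger low), dried ginger low replicate 2: 542 (dried ginger low) and 29 (fresh against dried ginger low), dried ginger low replicate 3: 33 (dried ginger low) and 3 (fresh against dried ginger low), dried ginger medium replicate 1: 97 (dried ginger medium), dried ginger medium replicate 2: 106 (dried ginger medium), dried ginger medium replicate 3: 109 (dried ginger medium).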

Other observations

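The genes of this part were chosen after their values were seen, and no test here was planned. Genes that moved with dose in several extracts were counted across the label prefixes. In Sayeok-tang, both gingers and Scutellariae Radix together, 1124 genes were higher at the high than at the low dose in all 4, against 37.7 expected if the extracts were independent, and 1139 were lower, against 45.1. AQP3 rose by 2.49 to 4.53 and IGFBP1 by 2.46 to 3.65 in these extracts. In all 6 extracts with replicates, 30 genes rose, against 0.0156 expected, and 35 fell, against 0.0196. The former held CYP1A1, AKR1B10 (0.54 to 2.59), AREG, AKR1C1, PTGR1, ABCC2, CPT1A and GCLM, and the latter HMGCS1, FDFT1, IDI1 and FADS2 of sterol and fatty acid synthesis, and the complement regulator gene C4BPA. The expectation takes every gene as equally likely to be called in an extract, which was not checked, so it is no test of the overlap.

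Circadian clock genes were mixed at the high dose of Scutellariae Radix, 4 higher and 8 lower of 14 (5 and 8 adjusted over the list alone), with BHLHE40 at 1.61 ± 0.092 and DBP at -1.42 ± 0.156. Interferon response genes were mixed there too, 3 higher and 3 lower of 10, with OAS1 at 0.88 ± 0.081 and MX1 at -0.36 ± 0.11, and nuclear respiratory chain genes were called higher in 7 and lower in 5 of 26. None of these 3 lists was called by camera (adjusted p of 0.56, 0.87 and 0.95). In the low-dose library of Zizyphi Fructus, 1 of 26 nuclear respiratory chain genes was called higher (7 adjusted over the list alone), with a median of 0.13 at percentile 100 of the random lists. Ribosomal protein genes had the same median and percentile there, and that library carried a trend with transcript length (medians of 0.123 among the shortest and -0.173 among the longest 20% of genes), so these shifts are not read as specific to the lists.

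MARK2, a kinase gene, stood at 28.1 ± 3.4 CPM in the vehicle and was called higher at the high dose of 5 of the 6 extracts with replicates and at several lower doses, at 48.4 CPM in Sayeok-tang low, 52.6 in fresh ginger low, 50.3 and 53 in dried ginger medium and low and 44.1 in Bojungikgi-tang medium. CDKN1A was lower than the vehicle at the low doses of fresh ginger, dried ginger, Pinelliae Tuber and Scutellariae Radix, at 86.2, 87.1, 84.8 and 81.9 against 102 CPM. These comparisons share the 3 vehicle libraries, the only vehicle libraries used.

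Marker genes of other cell types summed to 7.89 to 27.2 CPM over the libraries for fibroblasts, 9.21 to 30.8 for endothelium and 0 to 0.451 for lung epithelium. The leukocyte list summed to 1190 to 2350 CPM and rested on LYZ (mean 1510 CPM), and the intestinal list summed to 335 to 539 and rested on VIL1 (mean 343 CPM).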
